A study of Drosophila melanogaster with 12 samples.

How the data were processed

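RNA was measured in forelegs of male Drosophila melanogaster in 12 libraries, 3 biological replicates for each of the strains CO13N, CS and RG11N and of a CS/CO13N hybrid. The labels describe polyA-selected RNA, extracted with PicoPure and TriZol, and Nextera XT libraries. The values used are the raw counts per FlyBase gene that the authors deposited; per the submitters' processing notes Subread and the genome build dm6 were used, with no version, role or settings. Whether counting was stranded, how reads that align to several places were treated and which annotation release was used are not stated. Genes that overlap or resemble another gene are therefore uncertain, and only some of them are marked where they are named. Reads were not realigned. Groups were taken from the labels, and no library was left out.

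Counts per library ranged from 26374831 to 36034966. Of 17807 gene identifiers, 17710 (99.46%) had a symbol in the reference annotation, Ensembl BDGP6.54.115, the same assembly as dm6, which also gave positions and gene types. The 97 others held 0.475% of the counts and stayed in the fit. Reaching 3 counts takes 0.0833 to 0.114 CPM in a single library. Where a group had no count, a ratio is given as at least the other group's level over 3 counts in the pooled libraries of that group. Where a group had 1 to 3 counts the ratio comes with a 95% interval. Floors and intervals cover counting error only, not the spread between flies.

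Differences were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr at a minimum count of 10 (10996 genes kept), and robust quasi-likelihood F tests in 1 model of 4 strain means with 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no minimum fold. The comparisons were the 6 pairs of genotypes, the mean of CO13N and the hybrid against the mean of CS and RG11N, and the hybrid against the log2 mean of CO13N and CS. Genes called the same way in all 4 pairs of a selective with a promiscuous genotype were counted apart. The p of the averaged contrast measures the spread of libraries within strains, and with 2 genotypes per class it says nothing about other selective or promiscuous strains. Values after ± beside a log2 fold change are approximate standard errors from the F statistic, and beside CPM they are standard deviations of 3 libraries. CPM of single genes used library sizes scaled by TMM, sums over lists and the antennal genes used total counts, and log2 CPM a prior count of 2.

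The 35 gene lists (receptor, enzyme, tissue and pathway genes) and 14 single genes were fixed before the data were examined. Lists with at least 5 tested genes, 32 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with the correlation estimated from the data and with fry; all p-values were adjusted over the lists of a comparison, and genes of a list also over that list alone. camera shifted 8, 7, 6, 5, 6, 3, 7 and 2 lists in CO13N versus CS, CO13N versus RG11N, hybrid versus CS, hybrid versus RG11N, RG11N versus CS, hybrid versus CO13N, selective versus promiscuous and the mid-parent contrast. With an estimated correlation it shifted 0 in each (lowest adjusted p 0.54), and for selective versus promiscuous also 0 at an unadjusted p under 0.05, while fry gave 0 adjusted and 6 unadjusted. Genes named in the report are the 14 fixed genes, up to 10 per direction by fold among those called in all 4 pairs, up to 6 per direction by fold in each other comparison, and up to 4 called genes per list with the lowest p. The first of these rules required a mean log2 CPM of at least 0, and the next also that no library of a group overlapped those of the other. Genes outside these rules are said to be chosen or named after their values were seen.

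The position of the hybrid between CS (0) and CO13N (1) used log2 CPM means of genes called in CO13N versus CS. X-linked and autosomal shares were compared with Fisher's exact test, two-sided, with exact binomial intervals, which treats genes as independent although neighbouring genes are not. Expected overlaps assume independent draws from 10996 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for annotation and figures.

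The pipeline was tested on simulated data with 100 genes planted at 2-fold and 100 at 4-fold. In CO13N versus CS edgeR recovered 58% and 79% with 5 genes called that were not planted, DESeq2 62% and 83% with 28, and voom 50% and 68% with 5. In the averaged contrast edgeR recovered 72% and 84% with 8 not planted, and in all 4 pairs together 31% and 69% with 0. In 20 simulations with no effect, the averaged contrast called a mean of 0.4 genes and at most 2.

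Alternatives fixed beforehand were other size factors (RLE, upper quartile), no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, voom with quality weights, replicate number as a factor, fits to 2 strains alone, 2 groups of 6 libraries with no strain term, a minimum fold of 2, and leaving out each library in turn. Added after seeing the data were the log2 sums of the odorant receptor list and of the muscle list as covariates, and leaving out hybrid replicate 3 and RG11N replicate 3 together.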

Results

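Gene expression was measured by RNA sequencing in the forelegs of male Drosophila melanogaster, in 12 libraries that form 4 groups of 3 biological replicates. The groups are the strains CO13N, CS and RG11N, and a CS/CO13N hybrid. The series describes CO13N and the hybrid as selective and CS and RG11N as promiscuous. The main question is which transcripts differ between these kinds of male in the foreleg, which carries taste hairs that contact other flies. The labels do not give the direction or the generation of the hybrid cross. Total counts per library were 32081421 to 36034966 in CO13N, 29465372 to 34937679 in the hybrid, 26374831 to 30041530 in CS and 29916686 to 33469978 in RG11N. Of 17807 gene identifiers, 4172 had no count in any library and 10996 passed the filter on low counts. A count of 0 in a library allows a level of up to 0.0833 to 0.114 CPM, depending on the library. The most abundant transcript in each library, the mitochondrial ribosomal RNA mt:lrRNA, took 2.79 to 10.58% of the counts. Pearson's correlation of log2 CPM between replicates was 0.945 to 0.959 in CO13N, 0.936 to 0.942 in the hybrid, 0.924 to 0.932 in CS and 0.933 to 0.946 in RG11N.

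Lists of marker genes described what else the libraries held. The summed odorant receptor genes, which are known from the antenna and the maxillary palp, reached 88.6, 248 and 139 CPM in CS replicates 1, 2 and 3, 250.3 CPM in hybrid replicate 3 and 138 CPM in RG11N replicate 3. The other 7 libraries held 13.4 to 24.1 CPM of them. In the same 5 libraries the antennal protein gene Obp83a, chosen after its values were seen, stood at 341 to 1306 CPM, against 3.45 to 8.78 CPM in the other 7. Muscle genes varied within every strain, from 2014 to 22042 summed CPM, with 22042 CPM in CO13N replicate 1 against 3604 and 4122 CPM in the other CO13N libraries. Pan-neuronal genes summed to 11907 to 12641 CPM in RG11N and to 7994 to 10612 CPM in the other strains. The photoreceptor list held 378 to 498 CPM in all 12 libraries, of which the 5 opsin genes made up at most 2.43 CPM. Genes of testis and accessory gland summed to at most 2.4 CPM and genes of ovary and yolk to at most 6.1 CPM.

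**Figure D1:**
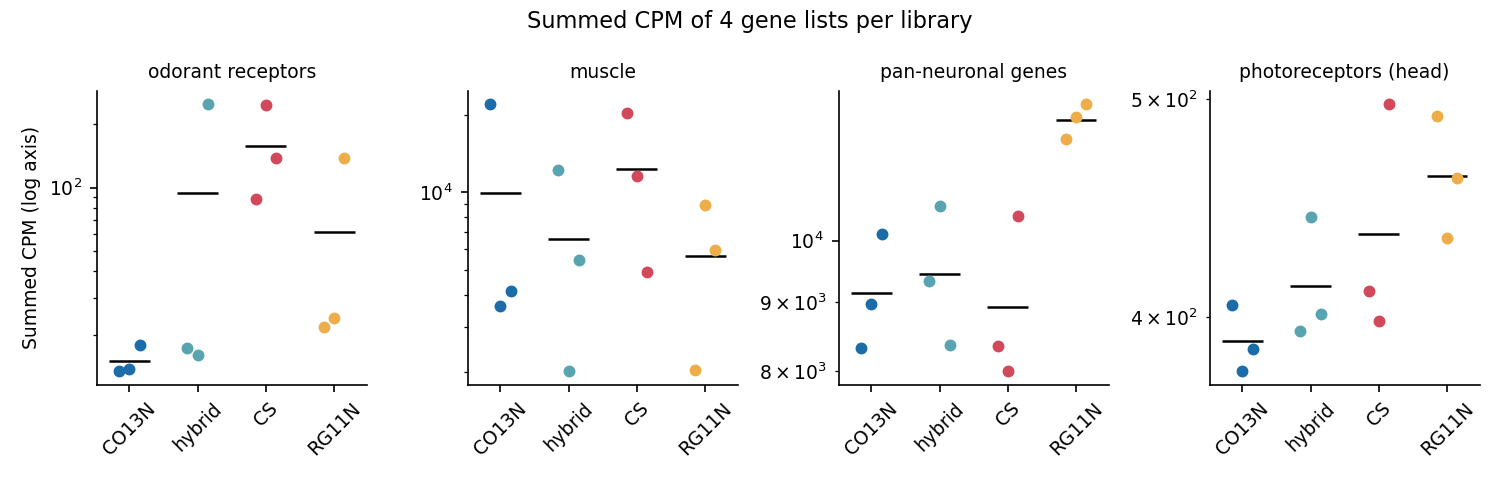
Summed CPM (log axis) of odorant receptor, muscle, pan-neuronal and photoreceptor genes in each of the 12 libraries, with 1 point per library and a bar at the mean of each strain. Odorant receptor genes stood at 88.6 CPM or more in 5 libraries and at 24.1 CPM or less in the other 7.

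Genes that separated both selective from both promiscuous genotypes were the closest match to the question of the series. In all 4 pairwise comparisons 20 genes were higher and 3 were lower in the selective genotypes. CG33282 (FBgn0053282, chromosome 2L, 3327903 to 3329792) had 1163 counts in CO13N, 799 in the hybrid and 0 in CS and RG11N, and was at least 601-fold higher. CG14568, CG14569 and CG14573, which lie within chromosome 3L 21730725 to 21734788, had 867, 658 and 501 counts in the selective libraries and 0 in the promiscuous ones, and were at least 265-fold, 201-fold and 153-fold higher. CG43291 (chromosome 3R, 14234984 to 14244677) had 1658 counts against 1, a ratio of 1520 with a counting interval of 273 to 60200. CG15322 on the X stood at 5.89 CPM ± 1.07 in CO13N and 7.59 ± 0.969 in the hybrid (SD, n = 3 for each), against 0 in CS and 0.913 ± 0.69 in RG11N.

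TotX, a member of the Turandot family of secreted stress peptides (chromosome 3R, 20904917 to 20905518), stood at 187 CPM ± 42.7 in CO13N and 43.5 ± 10.1 in the hybrid, against 6.23 ± 4.24 in CS and 6.5 ± 1.84 in RG11N (SD, n = 3). Acsx4 (chromosome 3R, 19783522 to 19785519) stood at 52.4 CPM ± 6.91 and 33.2 ± 1.6 against 4.58 ± 1.73 and 11 ± 1.76, and every selective library was above every promiscuous one. kumpel was higher by 1.99 ± 0.23 on the log2 scale (standard error), with 34.5 and 30.1 CPM against 5.92 and 11.1 CPM. CG18853 was higher by 2 ± 0.19 and overlaps the end of Prosalpha1R on the opposite strand. Prosalpha1 and Prosalpha1R, both also among the 20 and named after their values were seen, are close copies. All 3 are uncertain where counting ignored strand or shared reads. Among the 3 lower genes, Obp57e, an odorant-binding protein of leg taste hairs (chromosome 2R, 20547816 to 20548291), stood at 50.4 CPM ± 3.18 in CO13N and 70.9 ± 15.9 in the hybrid against 132 ± 22.1 in CS and 118 ± 30.2 in RG11N. CG43902 and the pseudogene CR43211, both on the X, differed by -0.69 ± 0.1 and -1.13 ± 0.15.

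Pairing CO13N and RG11N against the hybrid and CS gave 12 genes. Pairing CO13N and CS against the hybrid and RG11N gave 0. Both need a call between the hybrid and CO13N, which differed in only 28 genes. The pairing with 0 also needs the hybrid to lie outside both of its named parents. Neither is therefore a fair yardstick for the 23. The 20 simulations with no effect gave 0, but they held no difference between strains. CO13N is a parent of the hybrid, so the 2 selective genotypes share alleles by descent and are not independent examples of selective males. Leaving out any 1 library kept 10 of the 23 genes, among them CG33282, CG14568, CG43291, Acsx4 and CG18853. TotX and Obp57e each dropped out in 9 of the 12 omissions, CG14573 and CG43902 in 8 and CR43211 in 5, and without hybrid replicate 2 the count was 14. With the odorant receptor sum as a covariate, added after seeing the data, 15 of the 23 remained, and TotX, Obp57e, CG14573, CG43902 and CR43211 were among those lost. CG14573 was also lost with the muscle covariate and with replicate number as a factor. voom also kept 15, without CG33282, CG43291 and Obp57e, and a stricter filter on low counts removed CG14568, CG14569 and CG14573.

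**Figure D2:**
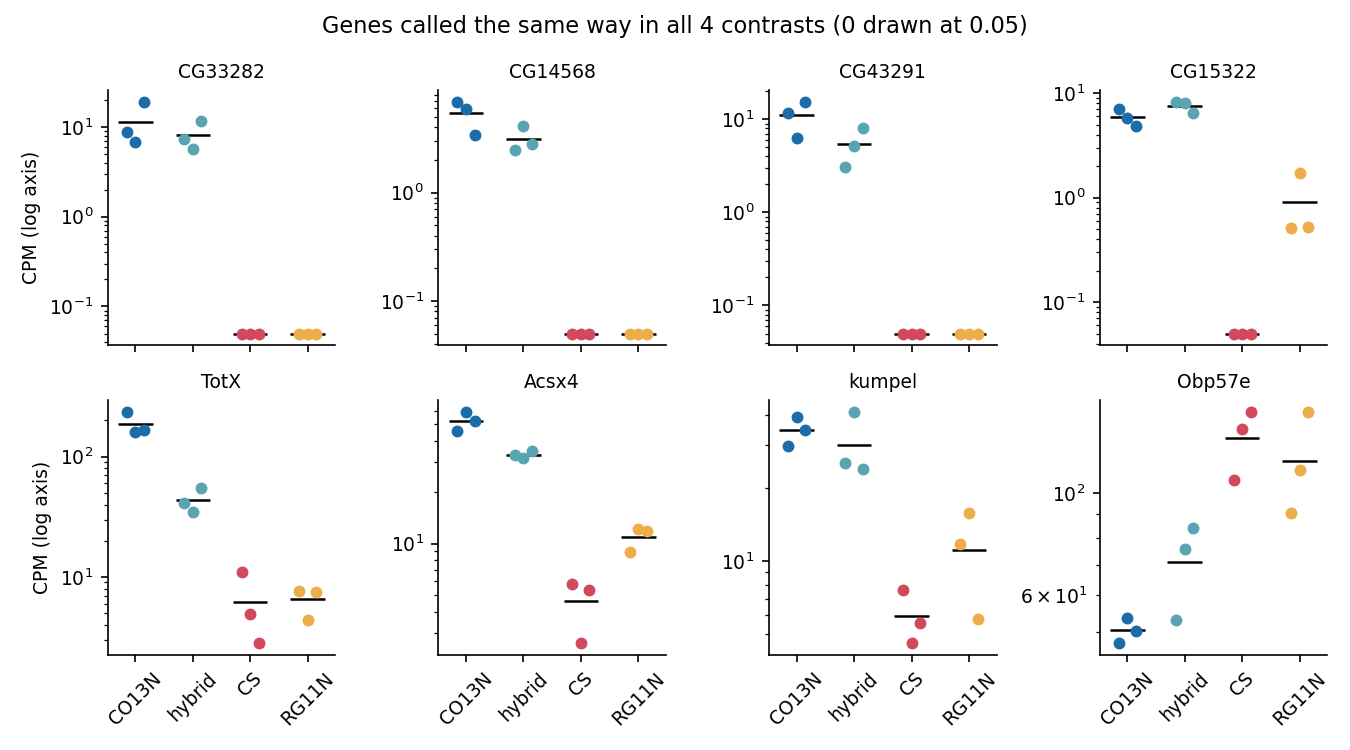
CPM (log axis, 0 drawn at 0.05) of 8 genes called the same way in all 4 comparisons of a selective with a promiscuous genotype, with 1 point per library and a bar at the mean of 3 replicates. TotX stood at 187 and 43.5 CPM in CO13N and the hybrid and at 6.23 and 6.5 CPM in CS and RG11N, while Obp57e ran the other way.

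The averaged contrast of the selective with the promiscuous genotypes called 431 genes, 286 higher and 145 lower, and 152 of them differed at least 2-fold. The vesicular monoamine transporter gene Vmat, 1 of 13 tested genes of transmitter synthesis and transport and the only one called (1 adjusted over the list alone), was higher by 0.86 ± 0.14 (adjusted p = 0.00218), with 413 CPM ± 114 in CO13N, 434 ± 22.7 in the hybrid, 185 ± 35.3 in CS and 292 ± 73.8 in RG11N. Of 34 neurotransmitter receptor genes 2 were higher and 2 lower (2 and 3 adjusted over the list alone). The octopamine receptor gene Oamb (0.67 ± 0.11) and the dopamine receptor gene Dop2R (0.78 ± 0.16) were higher. The dopamine receptor gene Dop1R1 (-0.66 ± 0.14) and the serotonin receptor gene 5-HT7 (-1.05 ± 0.14) were lower. Dop2R stood at 33.7, 36 and 34.6 CPM in CO13N, the hybrid and CS and at 11.8 CPM in RG11N, and Dop1R1 at 23.6, 24.6 and 27 CPM and at 53.7 CPM in RG11N, so RG11N carries both differences. 5-HT7 stood at 9.21 and 12.8 CPM against 25.1 and 20.1 CPM. Oamb stood at 65.2 to 75.8 CPM in CO13N and at 28.1 to 39.2 CPM in CS, but the hybrid (56.3 to 59.7 CPM) overlapped RG11N (45.3 to 58.9 CPM). Of 24 neuropeptide genes Burs was higher and Proc lower (2 and 2 adjusted over the list alone). Burs, which encodes a subunit of the hormone bursicon, was however highest in RG11N (5.44 CPM), had 0 counts in CS and stood at 1.83 and 1.48 CPM in the selective genotypes.

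Pan-neuronal genes were lower as a list in the averaged contrast by camera's preset (adjusted p = 4.95e-05) but not with an estimated correlation (adjusted p = 0.802), and the selective genotypes were not below CS. The mean of the summed list was 9135 CPM in CO13N and 9438 in the hybrid, against 8925 in CS and 12300 in RG11N, so RG11N carries the shift of the sum. Of 19 tested, elav (-0.46 ± 0.1, adjusted p = 0.00727) and the synaptic gene cpx (-0.42 ± 0.11, adjusted p = 0.0369) fell, and 10 were lower adjusted over the list alone. cpx stood at 807, 812 and 856 CPM in CO13N, the hybrid and CS and at 1360 CPM in RG11N, while elav was lower in both selective groups (66.8 and 63.5 CPM) than in CS (81.5) and RG11N (98.7). Against CS, edgeR called 0 of the 19 in CO13N (2 at an unadjusted p under 0.05, DESeq2 1, voom 0) and 1 in the hybrid, Frq1, which was higher (0.81 ± 0.15) with a call that ended without CS 1, CS 2 or hybrid 2 (adjusted p up to 0.0742). Leaving out any of 7 libraries (CO13N 1 and 2, CS 3, hybrid 1 and 3, RG11N 2 and 3) ended the call of cpx, with adjusted p up to 0.0974. Of 24 voltage-gated channel genes edgeR called 0 (7 at an unadjusted p under 0.05, DESeq2 1, voom 0, and 0 adjusted over the list alone); camera's adjusted p was 0.000627 in the lower direction, or 0.802 with an estimated correlation. Among 12 glial genes moody (0.63 ± 0.11) and loco (0.61 ± 0.11) were higher (2 adjusted over the list alone), and the glial transcription factor gene repo differed by -0.08 ± 0.16.

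Chemosensory genes went both ways. Of 34 odorant-binding protein genes Obp8a (0.85 ± 0.21) and Obp56d (0.73 ± 0.15) were higher and Obp57e (-1.06 ± 0.14) and Obp56h (-1.92 ± 0.19) were lower (2 and 3 adjusted over the list alone), with camera's adjusted p at 0.0204, or 0.802 with an estimated correlation. Obp56h stood at 240 CPM in RG11N and at 19.7 to 30.9 CPM in the other 3 groups, and Obp8a at 4.63 CPM in RG11N and at 14.1 to 17.2 CPM in the others, so RG11N carries both. The list also holds antennal genes such as Obp83a and Obp83b, which stood high in the libraries with high odorant receptor sums, all 3 CS libraries among them. Of 20 CheA and CheB genes, a family known from leg taste hairs, CheB38a (0.98 ± 0.17) was higher and CheA75a (-0.56 ± 0.13) and CheB38b (-1.46 ± 0.29) were lower (1 and 4 adjusted over the list alone; camera's adjusted p was 0.00594, or 0.802 with an estimated correlation). CheB38a was highest in CS (494 CPM) and lowest in RG11N (34.5 CPM). Of 17 pheromone taste genes Obp57e was called (3 lower adjusted over the list alone). The channel genes ppk23, ppk25 and ppk29, which act in pheromone-sensing taste neurons, differed by -0.4 ± 0.13, -0.27 ± 0.16 and -0.06 ± 0.15 and did not pass. The nearest was ppk23, with an adjusted p of 0.0995, which fell to 0.0489 without CO13N replicate 3. It stood at 886 to 1310 CPM in CO13N, 779 to 1118 in the hybrid and 913 to 1401 in CS. In RG11N it stood at 1595 to 1840 CPM, so RG11N carries this difference and the selective genotypes overlapped CS. The receptor genes Gr32a, Gr33a and Gr39a differed by -0.45 ± 0.45, -0.11 ± 0.44 and 0.5 ± 0.49, and Gr68a, with 55 counts over the 12 libraries, was not tested. The courtship genes fru (-0.18 ± 0.1) and dsx (-0.21 ± 0.1) did not pass, with adjusted p of 0.416 and 0.285.

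edgeR called 0 of 33 gustatory receptor genes (3 at an unadjusted p under 0.05, DESeq2 3, voom 1), 0 of 38 ionotropic receptor genes (5 unadjusted, DESeq2 4, voom 0), 0 of 18 pickpocket channel genes (4 unadjusted, DESeq2 1, voom 0) and 0 of 11 genes of sex determination and courtship (1 unadjusted, DESeq2 0, voom 0), and 0 in each of these lists adjusted over the list alone. It also called 0 of 41 odorant receptor genes (6 unadjusted, DESeq2 7, voom 0, 0 adjusted over the list alone), whose camera adjusted p was 0.000191 in the lower direction, or 0.802 with an estimated correlation; the libraries with high sums are named above.

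Detoxification enzymes were called in both directions. Of 75 cytochrome P450 genes 6 were higher and 6 lower (12 and 8 adjusted over the list alone), among them Cyp6a2 (2.65 ± 0.38), Cyp12e1 (0.96 ± 0.16), Cyp4d20 (0.62 ± 0.09) and Cyp6a23 (-1.01 ± 0.09). The sign of Cyp6a23 comes from RG11N alone, with 53.9 and 34.7 CPM in CO13N and the hybrid, 21.4 in CS and 355 in RG11N, and it was higher in CO13N than in CS (1.33 ± 0.14). Cyp12e1 stood at 20.3 to 23.3 CPM in the other groups and at 6.98 CPM in RG11N. Cyp6a2 stood at 0.86 to 1.25 CPM in CS. Its level in hybrid replicates 1 and 2 (9.35 and 7.33 CPM) lay within that of RG11N (6.55 to 10.6 CPM), so CS carries much of its fold. Cyp4d20 overlapped between CO13N (206 to 232 CPM) and CS (170 to 218 CPM) and stood at 117 to 122 CPM in RG11N. Of 35 glutathione S-transferase genes 4 were higher and 6 lower (4 and 7 adjusted over the list alone), with GstE5 at 0.65 ± 0.11, GstT4 at 0.61 ± 0.09, GstD9 at -0.84 ± 0.14 and GstE1 at -1.03 ± 0.13. CS carries the call of GstE5, with 126 and 89.7 CPM in CO13N and the hybrid, 37.8 in CS and 122 in RG11N. RG11N carries those of GstE1 (102, 113 and 132 CPM in CO13N, the hybrid and CS, 365 in RG11N) and GstD9 (27.8, 34.5 and 38.2 CPM, 80.6 in RG11N). Of 22 UDP-glycosyltransferase genes Ugt49B1 (1.04 ± 0.13) and Ugt49C1 (0.74 ± 0.09) were higher and Ugt35C1 (-1.34 ± 0.22) was lower (3 and 2 adjusted over the list alone). Ugt49B1 was also among the 20 genes higher in all 4 pairwise comparisons.

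Immune and cuticle genes were higher where called. Among 24 antimicrobial peptide genes BomBc1 and BomBc2 (2.22 ± 0.35) were higher (4 higher and 1 lower adjusted over the list alone); BomBc1 had 0 counts in RG11N and stood at 21.5, 5.89 and 13.8 CPM in CO13N, the hybrid and CS. The related gene BomBc3 stood at 54.9 to 139 CPM in RG11N and at 8.81 to 32.6 CPM in the other groups. The folds of BomBc1 against RG11N are therefore uncertain where counting shared reads. Of 2 Turandot genes tested, TotX was called. Of 49 cuticle protein genes Cpr64Ac (3.11 ± 0.66), Cpr49Aa (1.88 ± 0.45) and Cpr51A (0.92 ± 0.19) were higher (3 adjusted over the list alone), and camera's adjusted p was 0.00594, or 0.802 with an estimated correlation. Cpr49Aa was no higher in the hybrid (3.03 CPM) than in CS (3.33 CPM). The calls of Cpr64Ac and Cpr49Aa each ended in some omissions of 1 library, with adjusted p up to 0.089 and 0.13. Of 17 mitochondrially encoded genes mt:ND4L fell (-0.97 ± 0.23; 3 lower adjusted over the list alone; camera's adjusted p was 2.99e-07, or 0.802 with an estimated correlation), and the summed list varied from 42508 to 140082 CPM between libraries.

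In each of the other lists at most 1 gene was called. Acsl was higher among 10 genes of oenocytes and cuticular hydrocarbons (0.31 ± 0.08, adjusted p = 0.0489), a call that ended in 11 of the 12 omissions. The clock gene cry was higher (0.5 ± 0.1, 1 of 8), and norpA of the photoreceptor list (-0.62 ± 0.09, 1 of 8), Mal-A6 of the midgut list (-0.63 ± 0.12, 1 of 12) and btv of the ciliated neuron list (-0.37 ± 0.1, 1 of 24) were lower. edgeR called 0 of 25 muscle genes (1 unadjusted), 0 of 11 hemocyte genes (1), 0 of 8 fat body genes (2), 0 of 10 tracheal genes (2), 0 of 15 heat shock genes (1), 0 of 82 cytosolic ribosomal protein genes (7) and 0 of 68 nuclear genes of oxidative phosphorylation (1), where DESeq2 called 1 fat body and 1 tracheal gene and voom 1 tracheal gene. Of testis and ovary genes, 1 and 4 passed the filter and 0 were called (0 unadjusted, DESeq2 0, voom 0). Mhc, Hml and VGlut, markers of muscle, hemocytes and glutamatergic neurons, differed by 0.13 ± 0.74, 0.63 ± 0.88 and -0.15 ± 0.14.

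The adjusted p of this contrast rests on the spread between libraries within strains, not between strains; in a model of 2 groups of 6 libraries with no strain term 144 genes were called. With the odorant receptor sum as a covariate 208 genes were called, and 197 of the 431 kept their call while all 431 kept their sign and the median log2 ratio of their folds to those without it was -0.02. The calls of Dop2R, Dop1R1, cpx, CheB38a, CheA75a, CheB38b, Obp8a, Burs, Proc, cry, btv, mt:ND4L, Acsl, Cpr64Ac and Cpr49Aa were among those that ended.

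**Figure D3:**
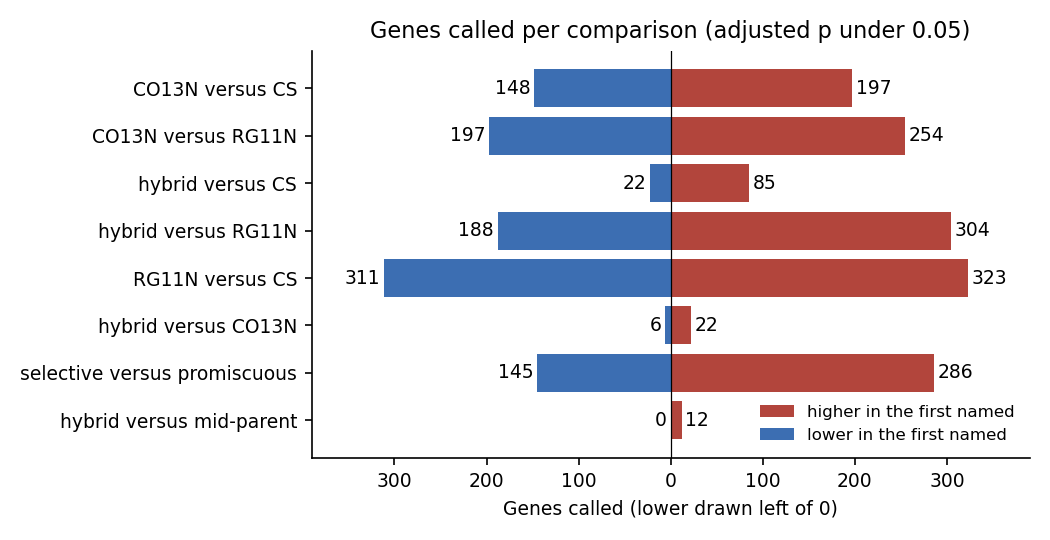
Number of genes called (adjusted p under 0.05) in each comparison, with genes higher in the first-named group to the right and lower to the left. RG11N versus CS called the most (323 higher, 311 lower) and the hybrid against the mid-parent the fewest (12 higher, 0 lower).

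CO13N and CS, a selective strain and a promiscuous one that are also the named parents of the hybrid, differed in 345 genes, 197 higher and 148 lower in CO13N. CG3397 (chromosome 3R, 11983098 to 11984541) had 1798 counts in CO13N and 0 in CS and was at least 502-fold higher. TotX was higher by 4.9 ± 0.52. The P450 gene Cyp6a20, which has been linked to male aggression, was higher by 1.44 ± 0.13 (491 against 181 CPM, adjusted p = 1.02e-06), and Cyp4d21, expressed in a sex-specific way, was lower by -1 ± 0.14. Cyp6a20 stood higher still in promiscuous RG11N (564 to 742 CPM, against 481 to 498 CPM in CO13N), so it does not separate selective from promiscuous males. Vmat was higher by 1.16 ± 0.21 (adjusted p = 0.00354), Oamb by 1.14 ± 0.16, and 5-HT7 was lower by -1.45 ± 0.21.

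By list, 2 of 34 neurotransmitter receptor genes were higher and 1 lower (4 and 2 adjusted over the list alone). Burs (at least 51.9-fold) was higher and sNPF (-0.98 ± 0.2) and Proc (-1.28 ± 0.3) were lower among 24 neuropeptide genes (1 and 2 adjusted over the list alone), with the call of Proc ending in 4 of the 12 omissions. Of 38 ionotropic receptor genes Ir40a (1.9 ± 0.29), Ir68a (5.06 ± 0.83) and the pseudogene Ir60c (at least 52.2-fold) were higher (3 higher and 1 lower adjusted over the list alone). Of 34 odorant-binding protein genes Obp57e was lower (-1.39 ± 0.2) and Obp56d higher (0.87 ± 0.22), the latter with a call that ended in 9 of the 12 omissions (1 higher and 6 lower adjusted over the list alone). Among glutathione S-transferases 4 were higher and 5 lower of 35 (7 and 5 adjusted over the list alone), with GstE5 at 1.74 ± 0.16 and GstE11 at -2.84 ± 0.21. CG6912 (-6.25 ± 0.39), Culd (-5.95 ± 0.5), the flight muscle gene TpnC4 (-5.38 ± 0.68) and asRNA:CR45600 (-7.9 ± 0.7, 7 counts against 1445) were lower in CO13N. Reads of the last cannot be told from those of its sense partner without strand. The antennal pheromone receptor gene Or67d had 0 counts in CO13N and 225 in CS and was at least 89.6-fold lower, but its call ended in 7 of the 12 omissions.

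The 3 CS libraries held 88.6 to 248 CPM of odorant receptor transcripts and the 3 CO13N libraries 13.4 to 17.9 CPM, so that this measure and the strain nearly coincide. With it as a covariate 98 genes were called, and 97 of the 345 kept their call. All 345 kept their sign, with a median log2 ratio of their folds of -0.08, so the folds stayed about as large. The calls of Vmat, Ir40a, Ir68a, Ir60c, Obp57e, sNPF and Proc ended. Without CO13N replicate 2, 206 genes were called, and DESeq2 called 657.

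CO13N and RG11N, a selective and a promiscuous strain, differed in 451 genes, 254 higher and 197 lower in CO13N. The methuselah-like receptor gene mthl8 had 3264 counts in CO13N and 0 in RG11N (at least 1020-fold higher), and the immune peptide gene BomBc1 had 2196 and 0 (at least 685-fold). TotX was higher by 4.84 ± 0.52, CheB38a by 2.74 ± 0.26 and Dop2R by 1.51 ± 0.23. The P450 gene Cyp6a23 was lower by -2.72 ± 0.14 (53.9 against 355 CPM, adjusted p = 5.36e-10), and GstD5 (-4.2 ± 0.44), GstE1 (-1.84 ± 0.18) and Obp56h (-3.19 ± 0.28) were lower. CG30049 had 0 counts in CO13N and 650 in RG11N and was at least 232-fold lower.

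Some neuronal genes were lower in CO13N and others higher, as Dop2R was. Of 19 pan-neuronal genes 6 fell and 0 rose (15 lower adjusted over the list alone; camera's adjusted p was 1.91e-08, or 0.729 with an estimated correlation), among them cpx (-0.76 ± 0.15), Nckx30C (-0.65 ± 0.14) and elav (-0.56 ± 0.14), while the summed list was 8315 to 10119 CPM in CO13N and 11907 to 12641 in RG11N. Leaving out CO13N 1, CO13N 2 or RG11N 2 ended the call of elav (adjusted p up to 0.11), and leaving out CO13N 1 that of Nckx30C (0.0592). Of 34 neurotransmitter receptor genes 5 were lower and 1 higher (7 and 2 adjusted over the list alone), with nAChRalpha3 at -2.17 ± 0.42, Dop1R1 at -1.19 ± 0.21 and 5-HT7 at -1.12 ± 0.2. The ionotropic receptor gene Ir52b, of foreleg taste neurons, was lower by -1.4 ± 0.25, and ppk23 (-0.63 ± 0.18, adjusted p = 0.0599) did not pass, with adjusted p of 0.0202 to 0.24 when single libraries were left out. Of 24 antimicrobial peptide genes 2 were higher and 1 lower (4 and 1 adjusted over the list alone; camera's adjusted p was 0.0147, or 0.729 with an estimated correlation). Without CO13N replicate 1, CO13N replicate 2 or RG11N replicate 2 the comparison called 271, 245 and 292 genes. DESeq2 called 851 with all libraries. edgeR called 262 without RG11N replicate 3 and hybrid replicate 3, which are the libraries outside CS with high odorant receptor sums. Fewer libraries alone also lower the count. With all libraries and the odorant receptor covariate it called 352, and 319 of the 451 kept their call.

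The hybrid and CS differed in 107 genes, 85 higher and 22 lower in the hybrid, the fewest of the 4 comparisons of a selective with a promiscuous genotype. CG33282 (at least 240-fold), CG3397 (at least 237-fold) and CG15322 (at least 216-fold) had 0 counts in CS. Vmat was higher by 1.23 ± 0.21 (adjusted p = 0.00604), Cyp6a2 by 3.9 ± 0.58, GstE5 by 1.25 ± 0.15 and Cyp6a20 by 0.88 ± 0.13. The hybrid (303 to 360 CPM) lay below RG11N (564 to 742 CPM) in Cyp6a20. The neuropeptide receptor gene sNPF-R was lower by -2.2 ± 0.33 (13.3 CPM ± 3.54 against 60.9 ± 6.69; SD, n = 3), CG32641 by -2.06 ± 0.26 and CG10031 by -1.8 ± 0.3. Of 34 neurotransmitter receptor genes Oamb (0.82 ± 0.16) and nAChRalpha3 (1.96 ± 0.43) were higher and 5-HT7 (-0.97 ± 0.2) was lower (2 and 1 adjusted over the list alone). Of 24 neuropeptide genes Burs was higher (at least 42.6-fold; 1 higher and 1 lower adjusted over the list alone). Of 75 P450 genes 5 were higher and 1 lower (7 and 4 adjusted over the list alone). TotX (2.8 ± 0.48) and Obp57e (-0.89 ± 0.19) lost their calls in 8 and 5 of the 12 omissions, nAChRalpha3 in 10, 5-HT7 in 4, Cyp6a2 in 3 (each CS library) and Oamb without CS replicate 2, with adjusted p up to 0.16. Without hybrid replicate 2, 65 genes were called, while DESeq2 called 234 and voom 61. The fit with the odorant receptor covariate called 70, and TotX, Obp57e, Oamb, nAChRalpha3 and 5-HT7 were not among them, while all 107 kept their sign with a median log2 ratio of their folds of -0.04.

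The hybrid and RG11N differed in 492 genes, 304 higher and 188 lower in the hybrid. mthl8 (3506 counts against 0, at least 1180-fold) and BomBc1 (549 against 0, at least 184-fold) were higher, as were CheB38a (3.07 ± 0.26), Cyp4p3 (2.98 ± 0.27) and Dop2R (1.61 ± 0.23). Cyp6a23 was lower by -3.36 ± 0.14 (34.7 against 355 CPM), GstD5 by -4.56 ± 0.44 and Obp56h by -3.61 ± 0.29. Of 19 pan-neuronal genes 7 fell and 0 rose (12 lower adjusted over the list alone; camera's adjusted p was 1.95e-07, or 0.818 with an estimated correlation), with cpx at -0.75 ± 0.15, elav at -0.64 ± 0.14 and brp at -0.62 ± 0.13, and the summed list was 8366 to 10612 CPM in the hybrid. Of 17 pheromone taste genes ppk23 (-0.82 ± 0.18, adjusted p = 0.0135), Ir52b (-1.5 ± 0.25), Ir52c (-0.86 ± 0.19) and Obp57e (-0.73 ± 0.19) were lower (5 adjusted over the list alone). Leaving out some single libraries ended the calls of ppk23 (hybrid 3, RG11N 2 and RG11N 3), Ir52c (hybrid 3 and RG11N 2), cpx (hybrid 3), elav (hybrid 2), brp (hybrid 3 and RG11N 2) and Obp57e (8 libraries), with adjusted p up to 0.169. Without hybrid replicate 2, hybrid replicate 3 or RG11N replicate 2 the comparison called 328, 264 and 288 genes, and DESeq2 with all libraries called 867. Without hybrid replicate 3 and RG11N replicate 3 together edgeR called 144, and the calls of ppk23, cpx, elav, brp, Ir52c and Obp57e ended. Fewer libraries alone also lower the count. With all libraries and the odorant receptor covariate edgeR called 503, and 465 of the 492 kept their call.

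RG11N and CS, both promiscuous, differed in 634 genes, 323 higher and 311 lower in RG11N. Strains of the same behavioural class can thus differ in this many genes, but a single pair gives no general size. Every CS library also held antennal transcripts, while RG11N replicates 1 and 2 had low odorant receptor sums. Cyp6a23 (4.05 ± 0.15, adjusted p = 2.62e-12), GstD5 (5.78 ± 0.47), Obp56h (2.96 ± 0.28) and nAChRalpha3 (3.75 ± 0.45) were higher in RG11N, as was Burs (511 counts against 0, at least 152-fold). mthl8 (0 counts against 1995, at least 743-fold), BomBc1 (at least 437-fold), CheB38a (-3.84 ± 0.27), Cyp4p3 (-3.47 ± 0.27), TpnC4 (-4.58 ± 0.65) and Dop2R (-1.55 ± 0.23) were lower. Of 19 pan-neuronal genes 6 rose and 0 fell (13 higher adjusted over the list alone; camera's adjusted p was 1.43e-06, or 0.787 with an estimated correlation), with Frq1 at 0.98 ± 0.15, cpx at 0.67 ± 0.15 and nSyb at 0.55 ± 0.13, and the summed list was 11907 to 12641 CPM in RG11N and 7994 to 10437 in CS. Of 17 pheromone taste genes Ir52b (1.85 ± 0.25), ppk29 (1.09 ± 0.21), Ir52c (0.99 ± 0.19) and ppk23 (0.66 ± 0.18, adjusted p = 0.0381) were higher (4 adjusted over the list alone). Of 38 ionotropic receptor genes 6 were higher (6 higher and 1 lower adjusted over the list alone), and of 35 glutathione S-transferase genes 7 were higher and 6 lower (7 and 9 adjusted over the list alone). Leaving out CS 1, CS 2, RG11N 2 or RG11N 3 ended the call of ppk23 (adjusted p up to 0.185), and leaving out CS 1, CS 2 or RG11N 3 those of cpx and nSyb (up to 0.0943). Without CS replicate 2, 378 genes were called. DESeq2 called 1051, a fit to these 2 strains alone 355, and the fit with the odorant receptor covariate 369, of which 349 were among the 634; all 634 kept their sign, with a median log2 ratio of their folds of -0.04. This count was the highest of the 6 pairs in the model of 12 libraries, a rank that some other fits, DESeq2 among them, kept and some lost. Fits to 2 strains alone gave 441 for the hybrid and RG11N and 383 for CO13N and RG11N, and voom gave 437 here against 506 and 452.

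The hybrid was closer to CO13N than to CS in its number of called genes. It differed from CO13N in 28 genes, 22 higher and 6 lower. CG6912 (5.42 ± 0.38, 20.9 against 0.483 CPM), Culd (5.25 ± 0.48), TpnC4 (4.19 ± 0.65), GstE11 (2.02 ± 0.21) and asRNA:CR45600 (6.81 ± 0.68) were higher in the hybrid, and all 5 were lower in CO13N than in CS. Arc1, which encodes a capsid-like protein that carries RNA between cells, was lower by -1.3 ± 0.17 (831 CPM ± 161 against 2050 ± 154; SD, n = 3; adjusted p = 0.000979), as were its relative Arc2 (-1.12 ± 0.18), Reck (-0.96 ± 0.16) and Ir40a (-1.61 ± 0.29). Of 35 glutathione S-transferase genes GstE11 and GstE2 were higher (3 higher and 1 lower adjusted over the list alone; camera's adjusted p was 0.000161, or 0.996 with an estimated correlation). Leaving out CO13N 2 or hybrid 3 ended the call of Arc2, CO13N 2, hybrid 2 or hybrid 3 that of Reck, and 5 single libraries each that of Ir40a and GstE2 (adjusted p up to 0.174). The count was 12, 13 and 15 without CO13N replicates 1, 2 and 3, and 10 and 7 without hybrid replicates 2 and 3. It was 8 without hybrid replicate 3 and RG11N replicate 3 together, 13 with the odorant receptor covariate and 93 in DESeq2. With the covariate all 28 kept their sign, and the median log2 ratio of their folds was -0.05.

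Against the mean of its named parents on the log2 scale, the hybrid was higher in 12 genes and lower in 0. edgeR gave 141 lower and 317 higher genes at an unadjusted p under 0.05, DESeq2 called 47 genes, 5 of them lower, and voom 0 (640 at an unadjusted p under 0.05). None of the 12 met the rule for named genes; named here after their values were seen, they are Alp4, CG15322, Culd, CG12224, CG3397, CG6912, Acsx4, NT5E-2, CG33282, CG43291, CR43377 and asRNA:CR45600. On the linear scale 10 of the 12 lay within 1.5-fold of the mean CPM of the parents, as CG3397 did with 8.3 CPM against 17.2 in CO13N and 0 in CS. The genes beyond that range, CG15322 (ratio 2.58) and CR43377 (1.53), both lie on the X. CG15322 alone had a mean above both parents, with 7.59 CPM against 5.89 and 0. It was not called between the hybrid and CO13N, and hybrid replicate 3 (6.47 CPM) lay below CO13N replicate 1 (7.02 CPM). None of ppk23, fru, dsx and elav departed from the mid-parent (log2 differences of -0.17 ± 0.16, -0.14 ± 0.13, -0.13 ± 0.12 and -0.22 ± 0.12, all with an adjusted p of 1). Without CO13N replicate 2, CS replicate 1, CS replicate 3 or hybrid replicate 3 the count was 20, 20, 21 and 8, and with no filter on low counts it was 20.

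Genes that differed between CO13N and CS were shared with the hybrid's comparisons. Of the 345, 98 were also called in the hybrid against CS in the same direction (79 higher, 19 lower) and 0 in the opposite one, where independent draws would give 1.52 and 0.3, and 20 simulations with no effect gave a mean of 0.05 and at most 1. Likewise 279 genes were called the same way in CO13N and in the hybrid against RG11N (180 higher, 99 lower). Independent draws would give 7.02 and 3.37, and the simulations gave a mean of 0.05 and at most 1. In both pairs the comparisons share their control libraries, and the 3 control libraries are too few to split. The simulations keep the shared libraries but hold no strain difference and no antennal transcripts in CS. A hybrid that shares alleles with CO13N would give more overlap from descent alone, so neither the simulations nor the independent draws test more than that. CO13N against CS and against RG11N shared 98 genes in the same direction and 14 in opposite directions. The hybrid against CS and against RG11N shared 25 and 13. These comparisons share the CO13N or the hybrid libraries, and their overlap was not simulated.

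On the X chromosome the hybrid lay near CO13N. Among genes called between CO13N and CS, the hybrid's log2 mean was nearer to CO13N than to CS in 41 of 41 X-linked genes (100%, exact binomial 95% interval 91.4 to 100) and in 196 of 301 autosomal genes (65.1%, 59.4 to 70.5), and Fisher's exact test, two-sided, gave p = 1.1e-07. On a scale from 0 at the CS level to 1 at the CO13N level, the median position was 0.86 for X-linked and 0.61 for autosomal genes, with 0.59, 0.56, 0.64 and 0.61 on 2L, 2R, 3L and 3R. Of 1870 X-linked genes edgeR called 0 between the hybrid and CO13N (52 at an unadjusted p under 0.05, DESeq2 1, voom 0), against 28 of 9044 autosomal genes (Fisher's exact test, two-sided, p = 0.00965). X-linked genes were also called less often between CO13N and CS (2.19% against 3.33%, the same exact test, p = 0.00866), so a lower share of calls on the X is not particular to the hybrid. Genes on a chromosome are not independent replicates, so these p-values describe the genes and not flies. Without CS replicate 3 the share on the X was 86.8% (33 of 38), with p = 0.0513 by the same exact test. With the odorant receptor covariate fewer genes were called, and it was 6 of 6 against 55 of 92 (exact test, p = 0.0802).

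**Figure D4:**
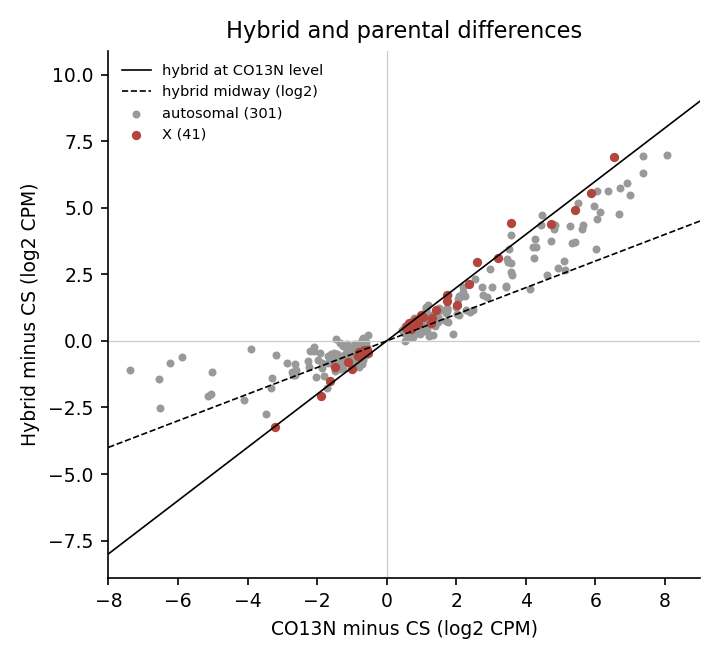
Difference of the hybrid from CS (vertical axis) against the difference of CO13N from CS (horizontal axis), both in log2 CPM with a prior count of 2, for genes called between CO13N and CS; red points are 41 X-linked and grey points 301 autosomal genes. The solid line marks the CO13N level and the dashed line the midpoint of the parents; the X-linked genes have a median position of 0.86 and the autosomal genes of 0.61.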

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

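The counts of called genes moved with the test, the covariate and the libraries used. DESeq2 called 657 genes in CO13N versus CS, 851 in CO13N versus RG11N, 234 in hybrid versus CS, 867 in hybrid versus RG11N, 1051 in RG11N versus CS, 93 in hybrid versus CO13N, 805 in selective versus promiscuous, 47 against the mid-parent and 58 in all 4 pairs, and kept at least all but 1 of the genes that edgeR called in every comparison; voom called 61 in hybrid versus CS and 0 against the mid-parent. The odorant receptor covariate, added after seeing the data, gave 98 in CO13N versus CS, 70 in hybrid versus CS and 369 in RG11N versus CS. It gave 352 in CO13N versus RG11N and 503 in hybrid versus RG11N. It gave 13 in hybrid versus CO13N, 208 in selective versus promiscuous and an X share of 100% (p = 0.0802, Fisher's exact test). Leaving out hybrid replicate 3 and RG11N replicate 3 together was also added later. It gave 262 in CO13N versus RG11N, 144 in hybrid versus RG11N and 8 in hybrid versus CO13N. RG11N versus CS fitted alone gave 355, selective versus promiscuous 144 as 2 groups of 6 libraries and 152 at a fold of at least 2, the mid-parent contrast 20 with no filter, and the lists 0 with an estimated correlation. Leaving out single libraries gave 206 (without CO13N 2) to 372 (RG11N 2) genes in CO13N versus CS, 245 (CO13N 2) to 524 (CS 3) in CO13N versus RG11N, 65 (hybrid 2) to 122 (RG11N 2) in hybrid versus CS, 264 (hybrid 3) to 572 (CS 3) in hybrid versus RG11N, 378 (CS 2) to 756 (CS 3) in RG11N versus CS, and 7 (hybrid 3) to 30 (CS 1) in hybrid versus CO13N. It gave 288 to 535 in selective versus promiscuous, 8 (hybrid 3) to 21 (CS 3) against the mid-parent, 14 (hybrid 2) to 27 (RG11N 1) in all 4 pairs, 86.8% (CS 3) to 100% for the X share, and 4 (RG11N 2) to 9 (RG11N 1) lists. Replicate number as a factor gave 380, 505, 112, 560, 669 and 26 genes in the 6 pairs. It gave 485 in the averaged contrast and 10 against the mid-parent. Over all genes the numbers paired libraries weakly at most. The mean correlation was 0.033 for the same number and -0.016 for different ones, and 6 of 12 libraries correlated best with their own number. Summed odorant-binding protein genes did rise from replicate 1 to 3 in every group, as from 25910 to 36965 CPM in CO13N and from 24006 to 34743 CPM in the hybrid. The labels name no batch, so a batch tied to the number stays possible. Of 438 named values 340 were called, and none of these changed sign in any setting. Leaving out some 1 library ended 127 of the 340 calls, and 213 kept their call whichever library was left out. The odorant receptor covariate ended 95.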

Other observations

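The tests in this part were chosen after the results were seen, except for the check of the X-linked genes against antennal RNA in CS and the regrouping of libraries for the gene lists. Genes that differ between CO13N and CS include 26 with at most 3 counts in 1 of these strains, 23 low in CS and 3 low in CO13N. CG3397, with 17.2 CPM in CO13N and 0 in CS, stood at 8.3 CPM in the hybrid, and CG43291, with 11.1 and 0, at 5.42. Over the 23 autosomal genes of this kind the hybrid held a median of 0.5 of the level of the expressing parent (interval 0.47 to 0.65), with 15 genes between 0.25 and 0.75. The set includes CG13313, Or67d and CG42816, which are low in CO13N and expressed in CS, with fractions of 0.84, 0.58 and 0.32. That of Or67d rests on hybrid replicate 3, a library with antennal transcripts (4.36 CPM, against 0.46 and 0 in the others). The median is consistent with a hybrid that carries 1 active copy of such genes, from the parent that expresses them. Called genes also lay next to each other: the 23 genes called in all 4 pairs included 4 neighbouring pairs (3 without overlapping genes) against a mean of 0.05 in random draws, and CO13N versus CS 39 against 10.78 (p = 1e-04 for each, the smallest possible with 10000 permutation draws). CG14568, CG14569 and CG14573 are such neighbours, as are Prosalpha1, CG18853 and Prosalpha1R, and together they make up the 4 pairs. The latter genes are uncertain where counting ignored strand or shared reads, and pairs that share a gene are not independent.

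Odorant receptor transcripts in 5 libraries might come from antennal tissue or RNA. The 13 antennal genes examined, among them Obp83a, Os-C and a10, were chosen after the pattern was seen and are not all antennal genes. They were higher by a median log2 difference of at least 5.95 in the affected hybrid and RG11N libraries than in the other libraries of the same strain. Head tissue with eyes is argued against, since the summed opsins differed by at most 0.91. A strain difference is argued against in the hybrid and RG11N, where 1 library differed from its replicates by at least 2.59 in the log2 odorant receptor sum. In CS all 3 libraries hold these transcripts, with the highest 2.8 times the lowest. The 13 antennal genes were present in each CS library as well. Os-C stood at 121 to 470 CPM and a10 at 139 to 435 CPM in CS, against 529 and 482 CPM in hybrid replicate 3. Antennal RNA and a strain difference could both give this. Hybrid replicates 1 and 2, from a cross with CS, held 17.3 and 16 CPM of odorant receptor transcripts and 0 CPM of Os-C. These values argue against a difference of CS that its alleles would carry into the hybrid. A strain difference that does not show in the hybrid stays open and was not tested.

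X-linked genes of the hybrid might lie near CO13N because the hybrid males carry the X of CO13N, as sons of CO13N mothers would. The difference of the X and autosomal shares (Fisher's exact test, p = 1.1e-07) is the pattern itself and does not test this. Mixing of CO13N flies or RNA into the hybrid libraries would by itself place autosomal genes at least as near CO13N. As the only cause it is argued against by a difference in median position of 0.25 (bootstrap interval over genes 0.15 to 0.34). The bootstrap treats genes as independent, and mixing in addition to another cause was not tested. Antennal RNA in CS is argued against, since p was 8.21e-07 by the same exact test with hybrid replicate 3 and 14 genes that differ in the antennal libraries left out. The direction of the cross is not given in the labels, so the X of CO13N stays an open, untested hypothesis.

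Genes above the log2 mid-parent might reflect the scale of the contrast rather than dominance. Over the 12 genes the hybrid held a median of 1.19 times the linear mean of the parents. Only the mean of CG15322 exceeded both, and that gene was not called between the hybrid and CO13N. Reads of CS alleles that fail to align to the reference could also leave genes at 0 in CS: 23 genes were low in CS and 3 in CO13N, and the counts alone cannot separate this from absent expression.

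Random regroupings of the libraries were drawn for the called genes of each comparison, the genes called in all 4 pairs and the lists, not for the shared genes or the X share. For each of the 6 pairs the real split was the largest, 1 of 10 splits, and 10 splits are too few to give a share under 0.05; the highest other counts were 130 in CO13N versus CS, 7 in hybrid versus CS, 6 in hybrid versus CO13N, 1 in RG11N versus CS and 0 in both other pairs. The averaged contrast as 2 groups of 6 gave 144 genes, 1 of 100 splits, with 2 as the highest other, and the other pairings of whole strains gave 0 and 63. The 23 genes called in all 4 pairs were reached in 1 of 100 splits, the real one, with 0 as the highest other. These regroupings of the 12 libraries mostly mix strains within a group. They can show that strains differ, but they cannot test the grouping into selective and promiscuous. For the 23 the other pairings of whole strains gave 12 and 0 genes, a comparison limited as said above, so chance is not excluded for that grouping. The 12 genes above the mid-parent were reached in 3 of 100, with 297 as the highest other, which could arise when a split separates real strains. The 7 lists were reached in 37 of 100, with up to 15 lists, so chance is not excluded for them; the cause was not tested.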
